A study of Mus musculus with 14 samples.

How the data were processed

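Polyadenylated RNA of mouse lymph-node dendritic cells (DCs) was measured by Smart-seq2 in 14 libraries of 150 sorted cells each. The libraries form 3 groups, 6 biotin-positive, 6 biotin-negative and 2 Cd40-null, and groups were taken from the sample labels. The labels give paired-end reads of 38 bp on a NextSeq500.

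Per the submitters' processing notes, the tools used were Bowtie2 2.1.0, RSEM 1.2.8 and DESeq2 1.16.0 with the mouse build mm10. The notes give neither the role of each tool nor the gene annotation. The authors deposited RSEM expected counts per gene, which are whole numbers in the table, for 23420 gene symbols. A second table that the authors deposited holds a normalized signal for 10321 genes. From the values, each entry equals the count divided by 1 factor per library, to within a relative deviation of 5.11e-15. The rule by which the genes of that table were chosen is not stated. Of the symbols, 27 are in a date-like form, as spreadsheet software makes from some gene names, and 2 of these names occur on 2 lines each; none is named below.

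The main test used the expected counts, rounded to whole numbers, in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group at a min.count of 10, which left 14217 genes; 3078 genes were at 0 in all libraries. Libraries were scaled with TMM factors. All 14 libraries entered one fit with a group factor (glmQLFit with robust=TRUE), and each pair of groups was tested two-sided with glmQLFTest. Genes past a Benjamini-Hochberg false discovery rate of 0.05 were called. Every adjusted p of a gene below is from this test unless another is named. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a common value of the library's scaled total), given as mean ± SD. Log2 CPM used a prior count of 2.

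Before the data were examined, 27 gene lists, the main tests, most alternatives and the rule for named genes were fixed. The rule took the 10 higher and 10 lower genes with the smallest p between biotin-positive and biotin-negative libraries, at a mean CPM of at least 5, and 5 each way for both other comparisons. It added Cd40 and up to 4 members with the smallest p of each list described, and passed over unnamed loci; some items it took are not reported here. Genes named outside the rule are said to be chosen after their values were seen. The 26 lists with at least 5 tested members were tested two-sided with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Single measures per library were compared with exact two-sided permutation tests. Gene positions are those of mm10 (GRCm38), 1-based.

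A score placed each library between the biotin groups. It is the mean log2 CPM over genes higher in biotin-positive libraries minus the mean over genes lower in them, with genes called in a fit of the 12 biotin-sorted libraries. For a biotin-sorted library, the genes were called without that library.

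Alternatives were other scaling factors, no filter and a stricter filter, a fit without the robust option, limma voom with sample quality weights, DESeq2 1.42.0, limma on the deposited normalized signal, a 2-fold threshold, only the 2 groups compared, the replicate number as a block, covariates, and each replicate left out in turn. The closing section gives their effect. The pipeline was tested on simulated counts for 14217 genes with 200 changed. Between biotin-positive and biotin-negative groups it recovered 22% of genes changed 2-fold and 55% of those changed 4-fold. The shares were 9.5% and 37.5% for biotin-positive against Cd40-null libraries, and 7.5% and 38% for biotin-negative against Cd40-null libraries. False calls numbered 0 to 3 in each simulation.

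Total counts ran from 1.45e+07 to 3.33e+07 per library. For a gene at 0 in a group, the limit used is 3 counts over the group's summed counts. Such floors cover counting error only, since reads of these libraries carry no molecular identifiers and are not independent molecules. Families of similar genes (H2, Klr, Apol7, Serpinb6, Lyz, Hspa1) are uncertain as single genes, because short reads are shared among their members. The labels do not say whether the libraries come from separate mice, so p-values measure the spread between these samples.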

Results

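The libraries follow a labelling method for cell contacts (LIPSTIC), in which the enzyme sortase A on one cell transfers a biotinylated peptide onto a pentaglycine tag on another. Here CD4 T cells of the OVA-specific OT-II line carried sortase on CD40 ligand, and DCs carried the tag on CD40. Peptide-pulsed DCs (5e+05 per footpad) were followed 18 hours later by 3e+05 T cells, given intravenously. The substrate (300 nmol per footpad) was given from 46 hours after T cell transfer, and popliteal lymph nodes were taken at 48 hours. The sequenced cells were endogenous DCs, high in MHC class II and positive for CD11c and CD11b but not XCR1, sorted as biotin-positive (6 libraries) or biotin-negative (6 libraries). A further group, with 2 libraries, came from Cd40-null mice given wild-type DCs and wild-type OT-II T cells, so genotype and transferred cells differ together. Without tagged CD40 these DCs could not be split by the label, whereas each biotin-sorted group is a fraction of its DCs.

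Total counts were 1.74e+07, 1.68e+07, 1.56e+07, 1.45e+07, 3.33e+07 and 1.91e+07 in biotin-positive replicates 1 to 6. They were 2.86e+07, 2.61e+07, 2.09e+07, 1.72e+07, 1.87e+07 and 1.68e+07 in biotin-negative replicates 1 to 6, and 2.38e+07 and 1.97e+07 in Cd40-null replicates 1 and 2. Biotin-negative libraries had counts for more genes, 14975.7 ± 621 (SD, n = 6), than biotin-positive libraries, 13295.8 ± 155 (SD, n = 6; exact permutation p = 0.00216, the smallest that 924 arrangements can give). After thinning to the smallest library the numbers were 14728.7 ± 588 and 13196.8 ± 141, with the same p. Cd40-null libraries had counts for 13354.5 ± 342 genes (SD, n = 2). The precursor of ribosomal RNA, Rn45s, took 17.7% ± 1.71 of counts in biotin-positive and 20.6% ± 0.747 in biotin-negative libraries (SD, n = 6 each; exact permutation p = 0.00216).

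Cd40, the receptor targeted in the null mice and tagged in the labelling, lies on chromosome 2 from 165055614 to 165071654. Its transcript was at 1062 ± 163 CPM in biotin-positive libraries (n = 6), 511 ± 78.7 CPM in biotin-negative libraries (n = 6) and 63.7 ± 14.7 CPM in Cd40-null libraries (n = 2). The null libraries held 74.2 and 53.3 CPM, both under the lowest biotin-sorted library, at 386 CPM. Cd40 was 2.08-fold higher in biotin-positive than biotin-negative libraries (log2 1.06, SE 0.13, adjusted p = 5.60e-05). Over the null libraries it was 16.7-fold higher in biotin-positive (log2 4.06, SE 0.23, adjusted p = 4.49e-08) and 8.01-fold higher in biotin-negative libraries (log2 3.00, SE 0.22, adjusted p = 1.76e-06). The labels do not give the exons removed by the null allele. The null mice also received wild-type DCs, so the source of the remaining transcript was not determined. With the number of detected genes as a covariate, the difference between the biotin groups kept its size (log2 1.06) but not its call (adjusted p = 0.202). The label is attached to CD40 itself, so sorting on it may select cells that had more CD40. This difference therefore does not by itself show an effect of contact with T cells.

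**Figure D1:**
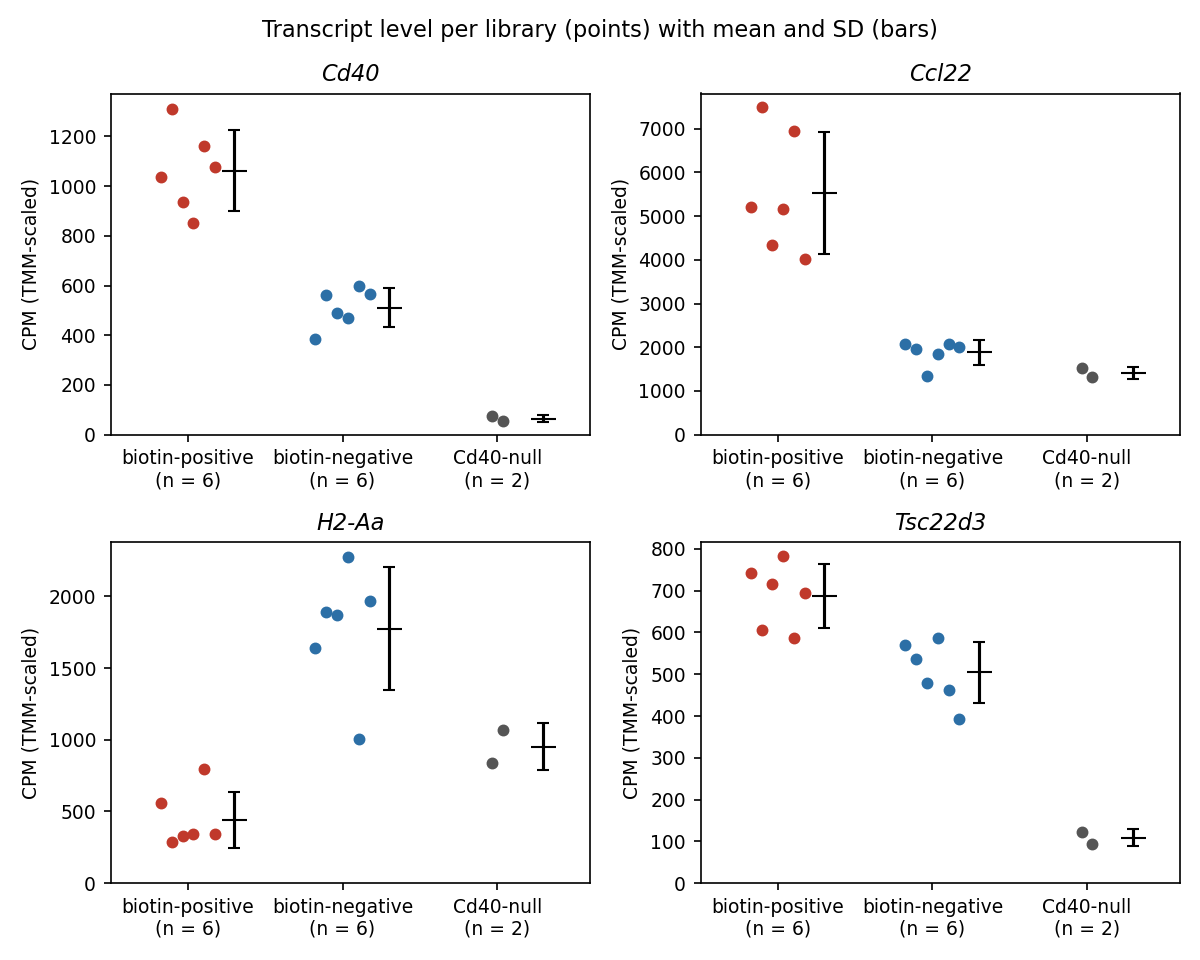
Each panel plots TMM-scaled CPM (y axis, from 0) per library for 1 gene in the 3 groups, with mean and SD beside the points. Cd40 and Tsc22d3 are lowest in both Cd40-null libraries, Ccl22 is highest in the 6 biotin-positive libraries, and H2-Aa lies between 1004 and 2278 CPM in biotin-negative and between 290 and 794 CPM in biotin-positive libraries.

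The comparison of biotin-positive with biotin-negative DCs asks how DCs that took up the label from CD40 ligand-bearing T cells differ from those that did not. The chemokine Ccl22, which binds CCR4, stood at 5526 ± 1400 CPM in biotin-positive and 1886 ± 283 CPM in biotin-negative libraries (n = 6 each), 2.93-fold higher (log2 1.55, SE 0.15, adjusted p = 1.13e-05; chromosome 8, 94745684 to 94751388). The actin-bundling gene Fscn1 rose from 3185 ± 376 to 7172 ± 932 CPM (log2 1.17, SE 0.10, adjusted p = 6.85e-06). The protease inhibitor Serpinb6b had the smallest p, at 1998 ± 136 against 836 ± 97.7 CPM (log2 1.26, SE 0.08, adjusted p = 4.58e-07; chromosome 13, 32956811 to 32979067). The MHC class II gene H2-Aa fell to 442 ± 197 CPM from 1776 ± 431 CPM (4.01-fold lower, adjusted p = 5.87e-05; chromosome 17, 34282744 to 34287823), and Mx1, annotated as a transcribed pseudogene in the reference genome, to 116 ± 30.7 from 440 ± 107 CPM (log2 -1.92, SE 0.18, adjusted p = 9.46e-06).

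Others reported among the 10 with the smallest p among higher ones were Snx11 (a sorting nexin, log2 1.56, SE 0.11), Tmem39a (1.36, SE 0.11), Epsti1 (0.88, SE 0.08) and Gtpbp1 (0.89, SE 0.09). Apol7c stood at 13140 ± 1543 against 5704 ± 749 CPM, 2.30-fold higher, and the lysosomal protease cathepsin B, Ctsb, at 1212 ± 161 against 543 ± 72.0 CPM. Among the 10 lower ones were Apobec1 (an RNA-editing deaminase, -1.77), Tspan3 (a tetraspanin, -0.98), Fabp4 (a fatty acid binding protein, -4.03), Arsb (a lysosomal sulfatase, -1.67), Pyhin1 (-1.73) and Htra1 (a serine protease, -1.70). Fabp4 stood at 3.31 ± 2.39 against 53.9 ± 10.9 CPM. The lectin-like receptor genes Klrd1 (-2.64), Klri2 (-2.79) and Klrk1 (-1.74) also fell. Of 14217 genes tested with edgeR, 1102 were called, 526 higher and 576 lower, and 541 of them differed at least 2-fold, 191 higher and 350 lower. With the number of detected genes as a covariate 11 genes were called and, of those reported among these 20 genes, Serpinb6b, Snx11, Tmem39a, Ccl22, Apobec1 and Fabp4 kept their call. DESeq2 called 1758 genes, and the mean level of T cell markers as a covariate left 667.

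**Figure D2:**
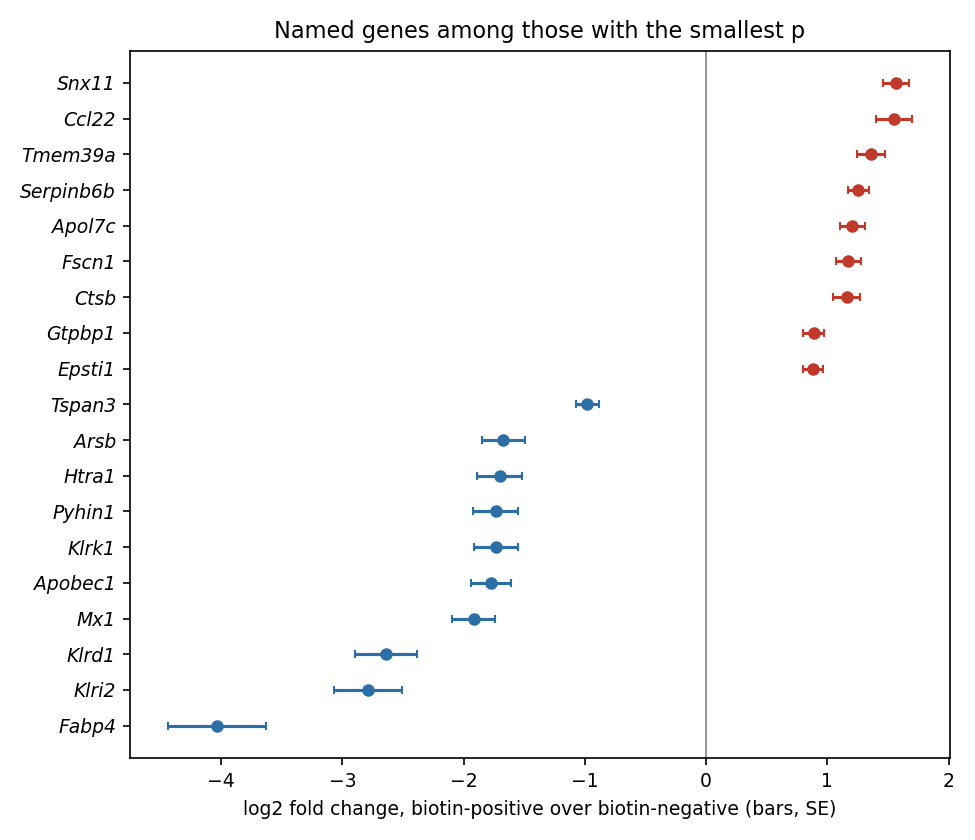
Points show log2 fold changes of biotin-positive over biotin-negative libraries (x axis; bars, SE; n = 6 each) for named genes, 9 higher and 10 lower, among those with the smallest p. The changes run from -4.03 for Fabp4 to 1.56 for Snx11.

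Genes of DC maturation went both ways: of 42 measured members 12 rose, 6 fell and 24 were not called (12 and 7 adjusted over the list alone). Fscn1, Ccl22, Serpinb6b and Apol7c were the 4 with the smallest p. The list ranked high in the camera test (adjusted p = 0.000166; adjusted p = 0.0938 with an estimated correlation), while its median log2 change was 0.01. Of 22 genes of MHC class I presentation 6 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.36e-06, and 0.106 as the adjusted p with an estimated correlation). They included the peptide-loading genes Tapbp (log2 0.67, SE 0.08) and Tapbpl (log2 0.94, SE 0.11). Of 23 genes of cholesterol synthesis 8 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 4.53e-11, and adjusted p = 0.0722 with an estimated correlation). Among these, squalene epoxidase Sqle stood at 137 ± 33.1 against 50.9 ± 19.8 CPM (log2 1.42, SE 0.24, adjusted p = 0.00136), and Fdft1 (log2 1.15, SE 0.19) and Hmgcs1 (log2 1.02, SE 0.22) also rose. The call of Hmgcs1 was lost with the T cell marker level as a covariate, and DESeq2 called 13 members of this list higher.

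Of 16 measured genes of MHC class II presentation 0 rose and 6 fell (1 and 10 adjusted over the list alone; camera adjusted p = 9.59e-10, and adjusted p = 0.0951 with an estimated correlation). H2-Ab1 (log2 -2.44, SE 0.35), H2-Eb1 (-2.20, SE 0.26) and the invariant chain Cd74 (-1.58, SE 0.21) fell with H2-Aa. In the type I interferon response 0 of 38 rose and 11 fell (0 and 13 adjusted over the list alone; camera adjusted p = 8.10e-08, and adjusted p = 0.0938 with an estimated correlation), among them Irf7 (log2 -3.16, SE 0.64) and Ifitm3 (-2.70, SE 0.36). Of 35 pattern recognition and endocytic receptors 0 rose and 15 fell (1 and 22 adjusted over the list alone; camera adjusted p = 2.68e-10, and adjusted p = 0.0604 with an estimated correlation), among them Clec12a (log2 -2.71, SE 0.45) and Tlr11 (-1.77, SE 0.34). Of 26 chemokines and chemokine receptors 1 rose, Ccl22, and 6 fell (1 and 11 adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.106 with an estimated correlation). Ccr2 was at 0.219 ± 0.121 against 24.7 ± 25.6 CPM; its call was lost with limma voom. Of 22 genes of DC tolerance and T cell inhibition 0 rose and 2 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.154 with an estimated correlation), with the cytokine-signalling inhibitor Socs3 at log2 -2.40 (SE 0.52). Limma voom called 2 chemokine and 6 tolerance genes lower, and DESeq2 9 and 5.

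Marker genes of some cell types also differed between the biotin groups. Of the monocyte and macrophage, Langerhans, NK, B and T cell lists, only the first had mean levels without overlap between the groups. Of 30 monocyte and macrophage markers 0 rose and 14 fell (0 and 20 adjusted over the list alone; camera adjusted p = 1.09e-13, and adjusted p = 0.0604 with an estimated correlation). Cd163, a scavenger receptor of macrophages, was at 0.627 ± 0.713 against 24.4 ± 12.1 CPM, and Ms4a6c fell by 2.65 on the log2 scale (SE 0.42). The mean log2 CPM of this list was 0.09 ± 0.465 in biotin-positive and 2.58 ± 0.892 in biotin-negative libraries (SD, n = 6 each), with no overlap, in the same libraries in which members of the class II, interferon and receptor lists fell. Of 18 markers of conventional type 2 DCs 1 rose and 8 fell (2 and 9 adjusted over the list alone; camera adjusted p = 3.90e-05, and adjusted p = 0.0719 with an estimated correlation), among them Sirpa (log2 -1.33, SE 0.23), the transcription factor Zeb2 (-2.41, SE 0.34) and Itgam, which encodes CD11b (-3.76, SE 0.89). Of 8 Langerhans cell markers 2 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00772, and adjusted p = 0.0719 with an estimated correlation). These were Epcam, at 149 ± 18.4 against 38.4 ± 16.4 CPM, and langerin, Cd207, at 105 ± 19.3 against 27.6 ± 15.8 CPM. Of 12 plasmacytoid DC markers 0 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000890, and adjusted p = 0.0938 with an estimated correlation), among them Spib (log2 -1.96, SE 0.31). Of 11 NK cell markers 0 rose and 4 fell, Klrk1, Klrd1, Klri2 and Ccl5, again with the same counts adjusted over the list alone (camera adjusted p = 2.66e-05, and adjusted p = 0.0719 with an estimated correlation). The mean log2 CPM of the NK list overlapped, from 0.43 to 1.98 in biotin-positive and from 1.01 to 3.50 in biotin-negative libraries. The list's mean log2 CPM was 1.38 ± 0.650 in biotin-positive and 1.73 ± 0.933 in biotin-negative libraries (SD, n = 6 each). Its median log2 change was -0.79, so both measures went in the direction of the 4 calls. The median of its members' mean CPM, 3.43 in biotin-positive and 1.77 in biotin-negative libraries, went the other way. Of 31 T cell markers 0 rose and 2 fell (1 and 2 adjusted over the list alone), Il7r (log2 -0.78, SE 0.14) and Il2ra (-1.19, SE 0.22), while the list's median was 1.35 (camera adjusted p = 0.0652). Limma voom called 9 monocyte and macrophage markers and 5 type 2 DC markers lower, and DESeq2 17 and 8; DESeq2 called 2 T cell markers and 2 type 2 DC markers higher.

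The comparison of biotin-positive with Cd40-null DCs sets labelled cells against cells that lack the receptor. Next to Cd40, Tsc22d3 differed with the smallest p, at 688 ± 76.9 CPM in biotin-positive (n = 6) and 109 ± 20.6 CPM in Cd40-null libraries (n = 2; log2 2.66, SE 0.19, adjusted p = 5.87e-07; chromosome X, 140539528 to 140600522). Tsc22d3 encodes the glucocorticoid-induced leucine zipper protein. Ushbp1 (chromosome 8, 71384274 to 71395834) was at 47.7 ± 18.5 CPM in biotin-positive libraries and at 0 in both null libraries, at least 703-fold higher against a floor of 3 counts over the null group (0.0678 CPM). Gramd3 (log2 1.60, SE 0.16) and Pik3r5, a regulatory subunit of phosphoinositide 3-kinase (log2 1.60, SE 0.17), were higher too. Lower in biotin-positive libraries were Mx1 (log2 -1.98, SE 0.23), Lrmp (-2.98, SE 0.35), the lysosomal cholesterol carrier Npc2 (-1.38, SE 0.16), Evi2a (-2.03, SE 0.26) and Limd2 (-1.22, SE 0.16).

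Between biotin-positive and Cd40-null libraries, 11 of 42 genes of DC maturation rose and 1 fell (16 and 3 adjusted over the list alone; camera adjusted p = 2.19e-07, and adjusted p = 0.148 with an estimated correlation). Cd40 is itself in the list and among the 11, where the null genotype fixes its direction. The list was not tested without Cd40 in any comparison. Ccl22 was 3.89-fold higher (log2 1.96, SE 0.23, adjusted p = 0.000255), Serpinb6b 1.95-fold (log2 0.97, SE 0.12) and Bcl2l14 5.67-fold (log2 2.50, SE 0.38). Cd86, a ligand of CD28, and Fscn1, both chosen after their values were seen, were higher by log2 1.23 (SE 0.19) and 0.98 (SE 0.15). Of 38 NF-kB target genes 5 rose and 0 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00285, and adjusted p = 0.294 with an estimated correlation), among them the survival gene Bcl2l1 (log2 1.82, SE 0.31). Of 11 NK cell markers 0 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000189, and adjusted p = 0.174 with an estimated correlation). Klrd1 was at log2 -2.33 (SE 0.31); the list's median was -0.98 and its mean 0.26, so these differ in sign. Of 18 markers of type 2 DCs 0 rose and 1 fell, Zeb2 at log2 -2.83 (SE 0.42; 1 and 7 adjusted over the list alone; camera adjusted p = 0.00128, and adjusted p = 0.174 with an estimated correlation). Of 30 monocyte and macrophage markers 0 rose and 1 fell, Lyz1 (0 and 5 adjusted over the list alone), at a median log2 of -1.20 (camera adjusted p = 1.80e-06, and adjusted p = 0.185 with an estimated correlation). Of 35 pattern recognition and endocytic receptors 0 rose and 1 fell, Clec12a (1 and 3 adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.263 with an estimated correlation). Of 16 MHC class II genes edgeR called 0 (6 at an unadjusted p under 0.05; 0 and 4 adjusted over the list alone), where DESeq2 and limma voom each called 3 lower (camera adjusted p = 0.00324, and adjusted p = 0.464 with an estimated correlation). Of 34 interferon-gamma response genes 0 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.00197, and adjusted p = 0.263 with an estimated correlation).

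In all, edgeR called 323 genes between biotin-positive and Cd40-null libraries, 174 higher and 149 lower. The count was 78 without null replicate 1 and 95 without null replicate 2; the call of Bcl2l1 was lost without either one, those of Cd86 and the class II list without replicate 2 and of Fscn1 and the NF-kB list without replicate 1. DESeq2 called 8 NF-kB target genes higher, and 5 monocyte and macrophage markers, 3 receptors, 3 type 2 DC markers and 5 interferon-gamma response genes lower; limma voom called 3 type 2 DC markers lower. Over all genes DESeq2 called 567 higher and 319 lower, limma voom 261 and 342, and limma on the deposited normalized signal 289 and 156.

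The comparison of biotin-negative with Cd40-null DCs sets unlabelled cells of the labelling mice against cells that lack Cd40. Tsc22d3 was 4.64-fold higher in biotin-negative libraries, at 505 ± 73.2 against 109 ± 20.6 CPM (n = 6 and 2; log2 2.22, SE 0.18, adjusted p = 6.20e-06). Ushbp1 was at 47.7 ± 23.1 CPM, at least 703-fold over the floor of the null group. Pdcd4, an inhibitor of translation (log2 1.79, SE 0.22, adjusted p = 0.000879), and the interleukin-7 receptor gene Il7r (log2 1.78, SE 0.22, adjusted p = 0.000879) were higher as well. Cd86 was 2.27-fold higher (log2 1.18, SE 0.18, adjusted p = 0.00635) and the NF-kB regulator Nfkbiz 4.11-fold (log2 2.04, SE 0.34, adjusted p = 0.0102). Lower in biotin-negative libraries were the junction gene F11r (log2 -0.83, SE 0.13), Apol7c (-0.72, SE 0.14), the cholesterol exporter Abcg1 (-0.63, SE 0.13), Gnb4 (-0.53, SE 0.11) and Mfge8 (-1.05, SE 0.21).

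Of 42 genes of DC maturation 2 rose, Cd40 and Cd86, and 1 fell, Apol7c, in biotin-negative against Cd40-null libraries (4 and 1 adjusted over the list alone and with DESeq2; camera adjusted p = 0.0102, and adjusted p = 0.464 with an estimated correlation). Of 30 monocyte and macrophage markers edgeR called 0 (7 at an unadjusted p under 0.05; 2 and 0 adjusted over the list alone), where DESeq2 called 3, all higher, and limma voom 0, and the median log2 was 1.44 (camera adjusted p = 0.00978, and adjusted p = 0.473 with an estimated correlation). The mean log2 CPM of this list was 1.61 and 1.66 in the null libraries, against 1.22 to 3.69 in biotin-negative ones. Of 35 pattern recognition and endocytic receptors edgeR called 0 (9 at an unadjusted p under 0.05; 1 and 0 adjusted over the list alone), where DESeq2 called 3, all higher, and limma voom 0 (camera adjusted p = 0.00369, and adjusted p = 0.464 with an estimated correlation). In cholesterol synthesis 0 of 23 rose and 0 fell, over all genes and adjusted over the list alone, at a median log2 of -0.46 (7 at an unadjusted edgeR p under 0.05; 0 called by DESeq2 and 0 by limma voom; camera adjusted p = 1.86e-05, and adjusted p = 0.464 with an estimated correlation). Of 31 T cell markers 1 rose, Il7r, and 0 fell (1 and 6 adjusted over the list alone), at a median log2 of -2.20 (camera adjusted p = 1.86e-05, and adjusted p = 0.464 with an estimated correlation). The mean log2 CPM of T cell markers was 2.71 in null replicate 1 and -0.08 in null replicate 2, against -0.66 ± 0.191 in biotin-negative libraries (SD, n = 6); without null replicate 1 the list was not called. In all, edgeR called 45 genes, 39 higher and 6 lower. The count was 21 without null replicate 1, 12 without null replicate 2, 6 with the number of detected genes as a covariate and 359 with DESeq2. Without null replicate 1, F11r, Abcg1, Gnb4, Mfge8, Nfkbiz and the DC maturation, monocyte and receptor lists lost their call, and without null replicate 2, Pdcd4, Il7r, Cd86, Nfkbiz and the 5 lower genes did. Without biotin-negative replicate 3, Apol7c, Abcg1, Gnb4 and Mfge8 lost theirs, replicates 1, 2, 4 and 6 each ended at least 1 of these 4 calls, and limma voom ended that of Ushbp1. With the number of detected genes as a covariate, Pdcd4, Il7r, Cd86, Nfkbiz and the 5 lower genes lost theirs, and with the replicate number as a block, F11r, Abcg1, Gnb4, Mfge8 and Nfkbiz did.

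For the score, Cd40-null libraries used 516 genes higher and 508 genes lower in biotin-positive libraries. Each biotin-sorted library used genes called without it. The score placed the Cd40-null libraries near the biotin-negative ones. It was 2.64 ± 0.457 in biotin-positive (SD, n = 6), 0.02 ± 0.245 in biotin-negative (SD, n = 6) and 0.54 ± 0.146 in Cd40-null libraries (SD, n = 2). The null libraries lay 0.52 above the biotin-negative mean, 20% of the distance between the biotin groups, and outside the range of either group (exact permutation p = 0.0357 against each, the smallest that 28 splits can give). Because null and biotin-sorted libraries were scored with differing gene sets, part of this offset may come from the sets. Null DCs could not be split by the label, and whether unsplit cells account for the offset was not tested. With the 50 genes of smallest p on each side, the difference was 0.59 (exact permutation p = 0.179).

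**Figure D3:**
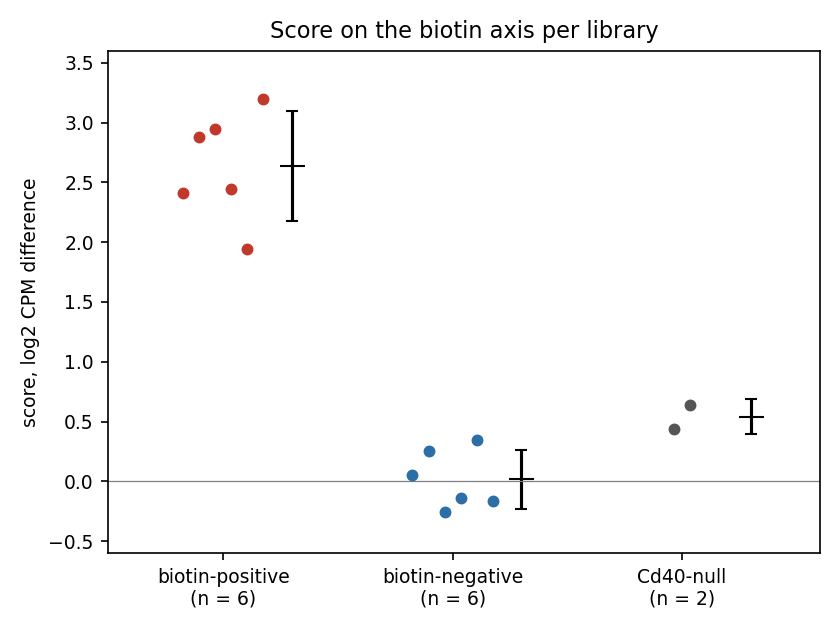
The y axis gives the score, a difference of mean log2 CPM, per library (points) with group mean and SD (bars) for 6 biotin-positive, 6 biotin-negative and 2 Cd40-null libraries. Biotin-positive libraries lie between 1.94 and 3.20, biotin-negative ones between -0.26 and 0.34, and Cd40-null ones at 0.44 and 0.64.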

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

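The tests of T cell transcript amounts, of the size of changes with the T cell marker covariate, of thinning, monocyte markers, neighbours of Cd40, glucocorticoid-induced genes and clock genes were chosen after the results were seen; the tests of other splits, the T cell marker covariate and the detected-gene covariate were planned.

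In groups of 6 libraries, 11 of 170 sets of values (genes named in the text and measures per library) had a library set apart by a wide gap, where chance gives about 8.5. Total counts of biotin-positive replicate 5 were 3.33e+07, with the next at 1.91e+07. In biotin-negative libraries, Ccl22 was at 1335 CPM in replicate 3 (nearest other 1848), Cd74 at 1648 CPM in replicate 5 (nearest 2666), and in replicate 2 Tapbpl at 389 CPM (nearest 315) and Ttpal at 29.1 CPM (nearest 43.8). Lyz1 was at 138 CPM in biotin-negative replicate 4 (nearest 57.2), and Naaa at 64.9 CPM (nearest 21.7) and Itgam at 65.0 CPM (nearest 30.4) in biotin-negative replicate 6. In biotin-positive replicate 6, Npc2 was at 314 CPM (nearest 436) and Lyz2 at 75.3 CPM (nearest 37.0). Hspa1a was at 672 CPM (nearest 309) in biotin-positive replicate 4.

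The genes higher in biotin-positive libraries, such as Ccl22 and Fscn1, may reflect the cells that received the label or RNA of T cells sorted with them. Only the real split, 1 of 100 drawn from 462, called as many genes, with 1024 in the 12 biotin-sorted libraries against at most 10 in any other split drawn. This argues against chance as the source of the calls, as far as 100 splits can show. It assumes independent libraries, which the labels do not state. With the T cell marker level as a covariate, 63.3% of the higher calls (333 of 526) were kept, short of the 80% set before the test was run for excluding T cell RNA, while the median log2 change of all 526 was 103% of that without it (0.83 against 0.81, median SE 0.19 against 0.16). That the median change of the higher calls did not shrink argues against T cell RNA as their whole cause, but only weakly. The marker level overlaps between groups only through biotin-positive replicate 4 (-0.59), which lies below biotin-negative replicate 6 (-0.31). Cd40-null replicate 1, at 2.71, also bears on the slope of the covariate. Part of a change from T cell RNA stays open. T cell markers, of which edgeR called 0 of 31 higher (11 at an unadjusted p under 0.05, DESeq2 2 higher, limma voom 0), had mean levels higher by a median of 0.930 CPM (at most 4.53 CPM), against 52.5 CPM for the higher calls. Of the 35 listed, with 0 in another list, only 6 had at least 5 CPM in biotin-positive libraries. The list's median log2 change was 1.35. The most abundant marker, Il7r at 282 ± 49.6 CPM, fell, but it stood far above the list's median, 1.82 CPM in biotin-positive libraries. Its fall therefore says little about the other markers. A difference in the DC subsets caught by the label stays open as a biological explanation. So does selection by the sort of DCs that already had more CD40, which carries the tag.

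The genes lower in biotin-positive libraries, such as H2-Aa and Clec12a, moved with a lower number of detected genes and lower monocyte markers. Thinning to equal total counts left the detected-gene difference in place (14728.7 against 13196.8 genes), as did thinning the counts outside Rn45s (14737 against 13190.7 genes), which argues against depth as its source. With the number of detected genes as a covariate, 0.907% of all calls were kept. The median log2 change of the lower calls went only from -1.29 to -1.20 while its median SE rose from 0.25 to 0.53, so the call ended by lost precision. This covariate cannot tell the 2 apart, because the groups do not overlap in detected genes. Cd40-null libraries had about as few detected genes as biotin-positive ones (13354.5 ± 342, n = 2, and 13295.8 ± 155, n = 6). Their score was 0.54 ± 0.146, against 2.64 ± 0.457 in biotin-positive and 0.02 ± 0.245 in biotin-negative libraries. For the score's genes as a set, higher and lower together, this argues against few detected genes as the whole cause. The score was not split by direction, so it does not settle this for the lower genes alone. Over Cd40-null libraries, the median log2 of the class II list was -0.35 in biotin-positive and 0.54 in biotin-negative libraries. It was -0.74 and 0.80 for receptors, -0.33 and 0.26 for the type I interferon response, and -1.20 and 1.44 for monocyte and macrophage markers. In these lists the null libraries lay between the biotin groups. Genotype, transferred cells and the split by the label differ there too. Monocytes or macrophages in the biotin-negative gate, which took CD11c- and MHC class II-high cells, also cannot be told apart from a change within DCs: with the marker level as a covariate 3.02% of the lower calls outside the list were kept (17 of 562; median log2 -1.25 before and -1.04 after, median SE 0.24 and 0.54), and that level does not overlap between groups either. Of the 32 markers listed, 7 are in another list and 8 had at least 5 CPM in biotin-positive libraries; the most abundant, Lyz2, chosen after its values were seen, was at 315 ± 280 CPM in biotin-negative and 35.6 ± 21.0 CPM in biotin-positive libraries.

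Genes lower in Cd40-null libraries than in both biotin-sorted groups, Tsc22d3 first, might come from the null allele, its neighbours, the mice's hormones or the time of day. Neighbours of Cd40 carried with the allele made up few of the calls. Within 20 Mb of Cd40, 3 of 298 tested genes, Bcl2l1, Serinc3 and Ttpal, were called against biotin-positive libraries (1.01%, elsewhere 2.33%, Fisher's exact p = 0.168). Against biotin-negative libraries 1 of 298, Serinc3, was called (0.336%, elsewhere 0.326%, Fisher's exact p = 0.627). Serinc3 and Ttpal, 1.43 and 1.45 Mb away, were chosen after their values were seen. The calls against biotin-positive libraries were lost without either null library, and that of Ttpal also without biotin-positive replicate 1, 3, 4, 5 or 6. The window held 298 of 13178 placed genes, so its size alone keeps its part of all calls low. Against biotin-negative libraries the odds ratio was 1.03 (95% interval 0.0254 to 6.10), too wide to exclude a raised share. For Bcl2l1, Serinc3 and Ttpal, carriage with the allele stays open. Lower glucocorticoid signalling cannot be told apart. After removal of the genes already called, 20 glucocorticoid-induced genes had a median log2 of 0.44 in biotin-negative over Cd40-null libraries (camera p = 0.0391, and p = 0.0854 with an estimated correlation). In biotin-positive over Cd40-null libraries it was 0.15 (camera p = 0.636, and p = 0.675 with an estimated correlation). The removal fixed the number of calls among them at 0, so that number is no evidence. At an unadjusted edgeR p under 0.05 were 5 and 3 of them. A rotation test (fry) passed its unadjusted threshold in the first comparison, and in both for change in either direction. A shift of the clock cannot be told apart either. Of 11 clock genes, again after removal of those already called, 1 had an unadjusted edgeR p under 0.05 in biotin-negative over Cd40-null libraries. In biotin-positive over Cd40-null libraries 2 did. Fry for change in either direction passed its unadjusted threshold in the latter comparison but not in the former. Genotype, transferred cells, the lack of a split by the label and any day of handling differ together in the 2 null libraries. A direct effect of Cd40 loss therefore stays open, as untested.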

How the results depend on the processing

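Leaving out the ribosomal RNA precursor and using the authors' gene set in edgeR were chosen after seeing the data; both left every count within 1.5 times. Over the 10 results that answer a comparison, 152 of 180 alternative values kept their side and size, 24 moved and 4 were weaker; over 179 single genes and lists, 3421 of 3838 values kept their call, 417 were weaker and 0 reversed. These genes and lists were mainly taken because they were already called, and were tested again in the same libraries. Few reversals could therefore arise. Between biotin-positive and biotin-negative libraries, 1102 called genes became 541 at a 2-fold threshold, 11 with detected genes as a covariate (10 of the 1102 kept), 667 with the T cell marker level as a covariate and 1758 with DESeq2 (1099 kept), and ran from 839 to 1106 without single libraries. Against Cd40-null, the 323 genes of biotin-positive libraries became 603 with limma voom, 196 at 2-fold and 886 with DESeq2, and ran from 78 (without null replicate 1) to 346 (without biotin-positive replicate 5), with 95 without null replicate 2. The 45 genes of biotin-negative libraries became 68 with the stricter filter (fewer genes tested), 83 with limma on the authors' table, 29 with only the 2 groups, 6 with detected genes as a covariate and 359 with DESeq2, and ran from 12 (without null replicate 2) to 48, with 21 without null replicate 1. Other than where fewer genes or samples entered, the cause was not tested. Cd40 between the biotin groups was at log2 1.06 with detected genes as a covariate (adjusted p = 0.202; 7.94e-12 to 0.00130 over its other alternatives). Gene lists called were 13, 12 and 11 in the 3 comparisons, 0, 0 and 0 by camera with an estimated correlation (12, 4 and 1 at an unadjusted p under 0.05), and 15, 4 and 0 with fry. Without null replicate 1, 3 lists were called between biotin-negative and null libraries; the range over libraries left out was 3 to 13. The null score difference of 0.52 was 0.59 with 50 genes a side (exact permutation p = 0.179), 0.63 without null replicate 1 and 0.42 without null replicate 2, where 7 splits cannot give a p under 0.143. With the replicate block, called genes were 891, 129 and 19 in the 3 comparisons. Same-numbered biotin-positive and biotin-negative libraries deviated together at r from -0.02 to 0.01, and 1 of 6 correlated best with its own number, so the numbers are not taken as pairs. In simulation at these depths and group sizes, with 200 of 14217 genes changed, 22% of 2-fold changes were recovered between the biotin groups. Depth and the number of changed genes, which lay below the 1102 called, were not varied there.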

Other observations

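The lists of glycolysis, oxidative phosphorylation, cell cycle and stress genes were not called by camera between biotin-positive and biotin-negative libraries. Of 20 glycolysis and hypoxia genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.463), the glycolytic regulator Pfkfb3 (log2 0.68, SE 0.10) and the enzyme Aldoa (log2 0.39, SE 0.09). Of 48 oxidative phosphorylation genes 2 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.750), Cox5a (log2 0.55, SE 0.12) and Atp5a1 (log2 0.41, SE 0.10). The calls of Aldoa, Cox5a and Atp5a1 were lost with the T cell marker level as a covariate. Of 36 cell cycle genes edgeR called 0, over all genes and adjusted over the list alone (4 at an unadjusted p under 0.05; camera adjusted p = 0.215), where DESeq2 called 3, all lower, and limma voom 0. Of 25 immediate early and stress genes 0 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.187), among them the chaperone gene Hspa8 (log2 -0.37, SE 0.06).

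Inflammatory genes went both ways between the biotin groups. Of 38 NF-kB target genes 5 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.215), with Irf1 at log2 0.69 (SE 0.12) and Nfkbiz at -1.57 (SE 0.22). Of 34 interferon-gamma response genes 4 rose and 2 fell (5 and 6 adjusted over the list alone; 6 and 5 with DESeq2; camera adjusted p = 0.635), with the transcription factor Irf8 at 437 ± 98.6 against 191 ± 47.2 CPM. Of 20 cytokines 1 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0579), among them Il1b (log2 -4.38, SE 0.83) and the interleukin-1 receptor antagonist Il1rn (log2 -2.58, SE 0.32). Of 13 markers of type 1 DCs 1 rose, Irf8, and 1 fell, Naaa at log2 -2.64 (SE 0.48; 1 and 3 adjusted over the list alone and with DESeq2, 2 and 2 with limma voom; camera adjusted p = 0.837). Of 19 B cell markers 0 rose and 2 fell, Blnk (log2 -1.06, SE 0.20) and Spib, with the same counts adjusted over the list alone (camera adjusted p = 0.354).

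Chosen after their values were seen, the glucocorticoid-induced gene Fkbp5 was at 34.9 ± 5.05 CPM in biotin-negative (n = 6) and 8.36 ± 4.16 CPM in Cd40-null libraries (n = 2; log2 2.06, SE 0.32, adjusted p = 0.00635), and the clock gene Per1 at 137 ± 39.3 against 36.2 ± 6.83 CPM (log2 1.92, SE 0.32, adjusted p = 0.0102). Serinc3, 1.43 Mb from Cd40 (chromosome 2, 163623273 to 163645149), was at 672 ± 93.5 against 257 ± 3.99 CPM (log2 1.39, SE 0.17, adjusted p = 0.000879). The calls of Fkbp5 and Per1 were lost without null replicate 2 and with the number of detected genes as a covariate, and that of Per1 also without null replicate 1. Heat-shock gene Hspa1a was at 279 ± 205 CPM in biotin-positive (n = 6) and 14.2 ± 7.03 CPM in Cd40-null libraries (n = 2; log2 4.30, SE 0.98, adjusted p = 0.0353); its call was lost without either null library, without biotin-positive replicate 3, with no filter and with limma voom.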
